A study of Mus musculus with 18 samples.

How the data were processed

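The data are RNA sequencing values from oocytes, cumulus cells (the somatic cells that surround the oocyte in the follicle) and blastocysts (the embryo before implantation) of C57BL/6 mice. Each of the 3 tissues was sampled from an exposure group that breathed fine particulate matter (PM2.5) and from a group kept in filtered air. There were 18 libraries in 6 groups of 3. Per the labels' protocols, the cells were lysed and reverse transcribed directly, the first-strand cDNA received a poly(A) tail from terminal transferase, and the cDNA was amplified before paired-end sequencing. The sources used here do not say whether the 3 libraries of a group came from separate animals or how many cells went into each. The p-values therefore measure the spread between these libraries, which may be technical in part.

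The authors deposited 1 table of log2 values, with 52550 genes and 21 columns, of which 18 hold the libraries. The deposited values are log2(x + 1), and the authors describe x as a normalized count. The values behave as if x had been scaled by transcript length. In 1010 genes with a single annotated transcript that were above 0 in 1 library only, the median of x was 0.104, and log10 x fell with log10 transcript length with a slope of -0.53 (SE 0.07). The slope was -0.78 (SE 0.05) for genes above 0 in all 18 libraries. A difference of deposited values is therefore a log2 fold change on the log2(x + 1) scale, which understates the change of low genes. Per the submitters' processing notes, FastQC, Cuffnorm and DESeq 1.22.1 were used with the mm10 build, with no order or role given. The aligner and the gene annotation are not given in the sources used here. A table of RefSeq genes on GRCm38.p6, which is the mm10 build, was matched by symbol for 35170 genes and gave coordinates and gene types. Transcript lengths came from an annotation of an earlier mouse build, from which no coordinates were taken. Of the symbols, 27 had been turned into dates and were replaced by gene identifiers, and 179 genes carried a symbol listed more than once.

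Read totals per library were not used here. The lowest values were checked for steps of whole reads, by counting how many genes with x under 0.5 shared the commonest ratio between a library and replicate 1 of the PM2.5 group of its tissue, in bins of 0.005 log2 units. A ratio counted as clear when it held at least 3 times as many genes as the highest count after shuffling, a bar set after such peaks had first been looked at. In cumulus cells all 5 ratios were clear, with 35 to 50 genes at the commonest ratio against 10 to 13 after shuffling. They put the depth of PM2.5 replicates 2 and 3 at 0.564 and 0.785 of that of replicate 1, and that of filtered-air replicates 1, 2 and 3 at 0.637, 0.865 and 1.08, each open to a factor of a small whole number. No ratio was clear in oocytes or blastocysts, where depth is unknown. Whole reads in all 6 libraries (tolerance 0.05 reads) were found for 401 of 14873 cumulus genes checked, or 2.70%, against 0.182% with random ratios. Read counts could therefore not be recovered, and no count model was run.

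PM2.5 was compared with filtered air in each tissue with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), on the 6 libraries of that tissue, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes were tested when their mean log2 value was at least 3 and at least 3 of the 6 libraries were above 0. Genes that passed are called changed by PM2.5, which names the comparison and not a proven cause. Whether the exposure difference itself differed between tissues was tested with limma as a difference of differences in a fit of all 18 libraries, over genes tested in both tissues. The 45 gene lists were fixed before the data were examined, of which 12 were markers of cell types or of sex. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. Members were also adjusted over the list alone. Fry tests whether a list's genes move one way, without comparing them with other genes.

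Genes were named by a rule written before the data were examined. In each tissue it takes genes past the threshold whose 3 exposed and 3 control libraries do not overlap and whose symbols are not predicted or clone names, up to 12 in each direction. Where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p were added, under the same rule for symbols, and they are said not to have passed. Up to 4 members per list and per marker list, and the 6 genes with the smallest adjusted p for each pair of tissues, were also named. Predicted genes were counted.

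The models were tested on simulated data drawn with the means and spread of the real genes, with 100 genes changed at each of 2 sizes. At a log2 change of 1 the oocyte comparison recovered 81% over 4080 genes, the cumulus comparison 72% over 4780 and the blastocyst comparison 64% over 4834. At a log2 change of 2 they recovered 96%, 97% and 91%. They made 8, 8 and 10 false calls. The test of a difference between oocytes and cumulus cells recovered 95.5% of 200 genes changed by a log2 value of 2 over 2027 genes, with 10 false calls. Noise was drawn independently for each gene, without shifts shared by the genes of a library. For the test between tissues, each gene had the same spread in all groups. Recovery and false calls in the real data may therefore differ.

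Alternatives covered the filter on low values, the scaling between libraries, the pseudocount, the mean-variance trend, library quality weights (limma with statmod 1.5.0), a block for the replicate number, the libraries in the fit, and leaving out each library in turn. Those added after seeing the data were a looser filter, protein-coding genes alone, a hemoglobin covariate in cumulus cells, leaving out both blastocyst libraries numbered 1, and all settings of the correlations between tissues.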

Results

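The series measured transcripts in mouse oocytes, cumulus cells and blastocysts to compare PM2.5 exposure with filtered air in each, with 3 libraries per group. Between 16426 and 17987 of the 52550 genes were above 0 in a library, and the depth behind the values is known only as ratios between the cumulus libraries. Within a group, libraries correlated across genes at 0.979 to 0.985 in oocytes, 0.975 to 0.980 in cumulus cells and 0.974 to 0.981 in blastocysts. Between the groups of a tissue the range was 0.979 to 0.984 in oocytes, 0.968 to 0.979 in cumulus cells and 0.975 to 0.979 in blastocysts, and between tissues 0.505 to 0.810. No pair of libraries shared more than 0.00803% of its values, so none was treated as a duplicate. Mitochondrially encoded genes held 11.4% to 17.9% of the summed linear values in oocytes, 12.9% to 20.4% in cumulus cells and 14.7% to 23.3% in blastocysts.

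Markers of each tissue were expressed in it, though not every member of the lists was. Figla stood at a mean log2 value of 0.70 in exposed and 1.11 in control oocytes. Wt1 stood at 0.38 and 0.35 in cumulus cells and Hand1 at 0.21 and 0.51 in blastocysts. The oocyte growth factor Gdf9 stood at 11.26 ± 0.07 (mean log2 value ± SD, n = 3) in exposed and 11.09 ± 0.38 in control oocytes, and at 0.71 ± 0.28 and 0.52 ± 0.44 in blastocysts. The oocyte-secreted protein Oosp1 (11.08 ± 0.17 and 11.19 ± 0.09), the oocyte linker histone H1foo (10.70 ± 0.08 and 10.55 ± 0.14) and the growth factor Bmp15 (10.10 ± 0.20 and 10.17 ± 0.29) were likewise high in exposed and control oocytes. Among granulosa and cumulus markers, the inhibin subunit Inha stood at 8.70 ± 0.28 in exposed and 7.77 ± 0.12 in control cumulus cells, the activin-binding Fst at 7.25 ± 0.15 and 7.28 ± 0.19, Nr5a2 at 6.05 ± 0.17 and 5.99 ± 0.08, and Inhba at 6.03 ± 0.08 and 6.19 ± 0.22. Of the same list, the aromatase gene Cyp19a1 was higher in oocytes (4.05 ± 0.21 exposed, 3.88 ± 0.13 control) than in cumulus cells (1.54 ± 0.90 and 1.61 ± 0.61), and Kitl had similar levels in both (1.68 ± 0.52 in control oocytes, 1.77 ± 0.44 in control cumulus cells). Blastocysts expressed the trophectoderm keratins Krt18 (10.02 ± 0.33 exposed, 10.33 ± 0.42 control) and Krt8 (9.04 ± 0.33 and 9.48 ± 0.27), Cdx2 (6.24 ± 0.42 and 6.30 ± 0.10) and Id2 (8.29 ± 0.11 and 8.21 ± 0.31), the last at a similar level in cumulus cells (8.17 ± 0.24 and 8.01 ± 0.12), and the pluripotency genes Zfp42 (6.98 ± 0.12 and 7.05 ± 0.07) and Nanog (5.86 ± 0.38 and 5.67 ± 0.41).

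Cumulus libraries also held transcripts of other cells. Gdf9 stood at 3.88 ± 0.40 in exposed and 3.43 ± 0.23 in control cumulus cells, the macrophage lysozyme Lyz2 at 5.72 ± 0.63 and 5.65 ± 0.59, and the lymphocyte antigen Cd52 at 5.44 ± 0.64 and 4.71 ± 0.21. The mean of 4 hemoglobin genes differed between libraries of the same group, at 0.44, 7.30 and 1.24 in PM2.5 replicates 1, 2 and 3 and 5.77, 0.46 and 7.64 in filtered-air replicates 1, 2 and 3. Some markers of other cells separated the exposure groups, at low levels. The mean of the stromal and smooth muscle list was 0.66 ± 0.06 in exposed and 0.43 ± 0.03 in control cumulus cells and that of the oviduct epithelium list 0.41 ± 0.02 and 0.14 ± 0.06, with no overlap between groups. The oviduct glycoprotein Ovgp1 stood at 1.45 ± 0.48 and 0.11 ± 0.16 and the collagen Col3a1 at 1.06 ± 0.07 and 0.53 ± 0.16, with no overlap. Other members of these lists were no higher in exposed cells: Tagln stood at 0.56 ± 0.42 and 0.61 ± 0.51, Dcn at 0.04 ± 0.07 and 0.08 ± 0.08. The leukocyte list overlapped between groups (means of 2.44 to 2.76 exposed and 2.21 to 2.94 control). Of its members, Ptprc was higher in every exposed library (0.46 ± 0.14 against 0.18 ± 0.12) and the neutrophil calprotectin subunit S100a9 lower in every exposed library (0.61 ± 1.06 against 3.12 ± 0.97). The share of such cells may therefore differ between the exposed and control cumulus libraries. Among all tested cumulus genes 26.3% had groups that did not overlap, so separation of some markers is not particular to other cells.

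In oocytes, Pacsin2, which encodes a membrane-bending adaptor of endocytosis, was higher with PM2.5. It stood at 6.44 ± 0.91 against 2.33 ± 0.17 in controls (mean log2 value ± SD, n = 3), a difference of 4.11 (SE 0.41). The mitochondrial ribosomal protein gene Mrpl9 was also higher, at 5.54 ± 0.10 against 4.58 ± 0.06, a difference of 0.96 (SE 0.10). Transcripts that fell were Eps8, an actin-capping signaling adaptor, from 5.56 ± 0.16 to 3.09 ± 0.27, a difference of -2.47 (SE 0.17), and Neil3, a DNA glycosylase of base excision repair, from 6.21 ± 0.14 to 5.19 ± 0.13, a difference of -1.03 (SE 0.12). The co-chaperone Dnaja1 fell by 0.84 (SE 0.11) and the G protein subunit Gna14 fell by 0.80 (SE 0.09). The adjusted p from limma was 0.0144 for Pacsin2, 0.0206 for Mrpl9, 0.00203 for Eps8, 0.0247 for Neil3, 0.0400 for Dnaja1 and 0.0254 for Gna14. Eps8 lies on chromosome 6 from 137477245 to 137649397 and Pacsin2 on chromosome 15 from 83375607 to 83464610 (mm10). Pacsin2 also moved within groups of another tissue, at 0.30, 4.61 and 4.64 in the 3 exposed cumulus libraries and 4.61, 0.16 and 0.40 in the 3 control ones.

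In all, 9 of 4080 genes passed the threshold in oocytes, 2 higher and 7 lower, and 3 of those that fell were predicted genes. With quantile normalization the split was 4 higher and 7 lower. At an unadjusted p under 0.05 there were 340 genes, against 204 by chance, and 626 genes (15.3%, against 10% by chance) had groups that did not overlap. The next 5 in each direction did not pass. Their differences were 1.67 for the mitochondrial import chaperone Timm10, 1.01 for Cdk16, 0.83 for Naa30, 0.70 for the iron-sulfur scaffold Iscu and 1.14 for Dstyk. In the other direction they were -0.82 for the glutathione peroxidase Gpx3, -0.87 for Zdhhc5, -0.85 for Ldlrad4, -0.66 for Skp1a and -0.76 for Dennd4c, with limma adjusted p from 0.0624 to 0.170. Without filtered-air replicate 1 the count was 3 and without filtered-air replicate 3 it was 2; in the second case Pacsin2 had an adjusted p of 0.0656.

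**Figure D1:**
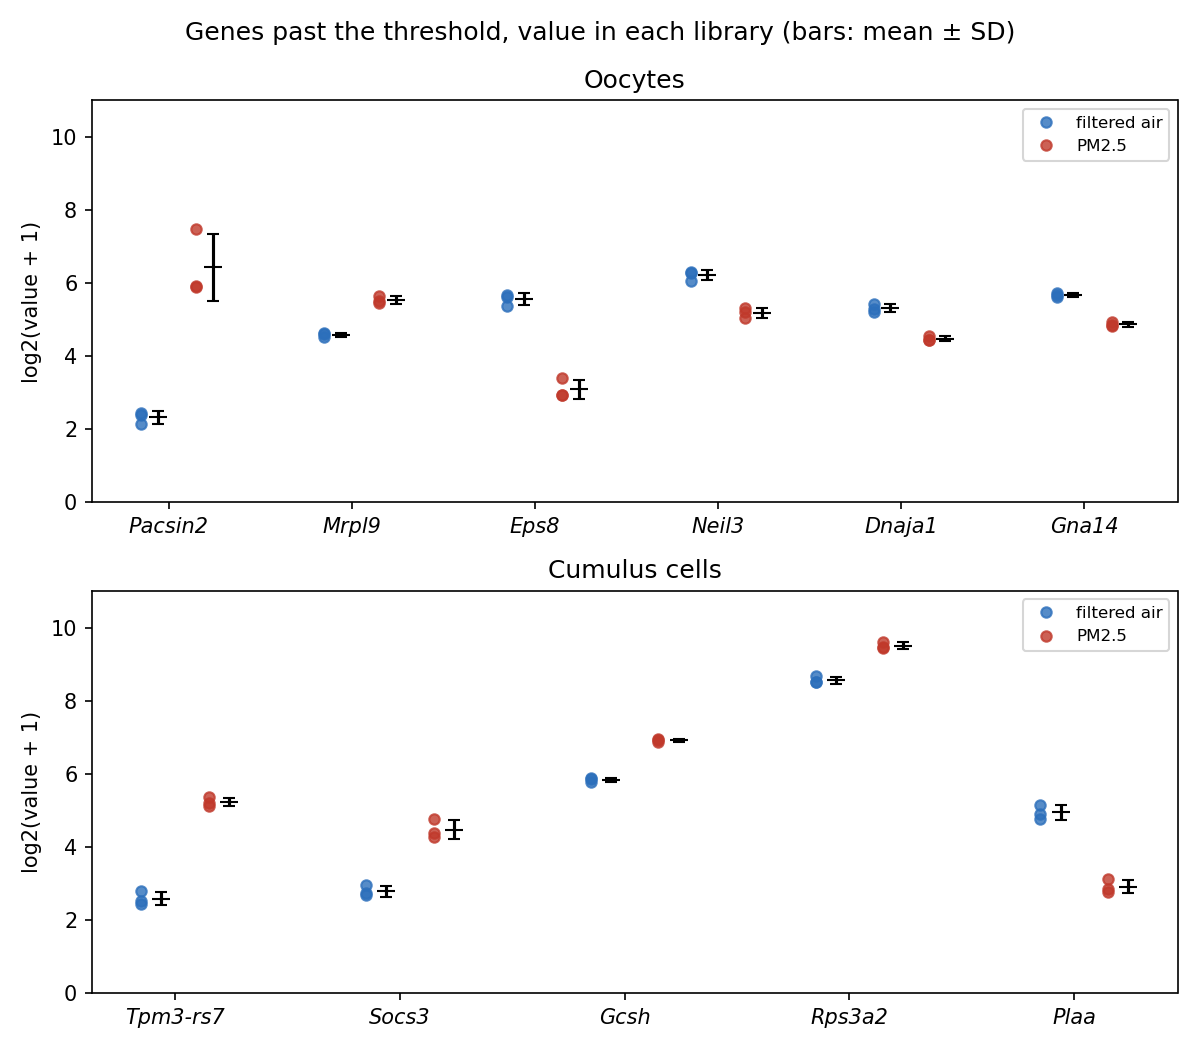
Each point is the deposited log2(value + 1) of 1 library for the named genes past the threshold in oocytes (top) and cumulus cells (bottom), red for PM2.5 and blue for filtered air, with bars for the mean and SD of 3 libraries. No gene shown has overlapping groups; the Pacsin2 values of exposed oocytes lie between 5.91 and 7.49 and those of controls between 2.13 and 2.46.

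Of 22 lists tested in oocytes, the transcripts encoded by the mitochondrial genome rose together: 13 of 15 were higher, with a median difference of 0.37 (camera adjusted p = 2.1e-07). The adjusted p was 0.747 with an estimated correlation and 0.402 with fry. Of the 10 splits of the 6 oocyte libraries, the real one included, 9 gave at least 1 list past the threshold. The smallest p values were those of mt-Co2 (0.58, SE 0.14), mt-Nd4 (0.57, SE 0.17), mt-Nd1 (0.54, SE 0.18) and mt-Cytb (0.55, SE 0.20), subunits of the respiratory chain, and no member passed over all genes or adjusted over the list alone. Filtered-air replicate 3 stood apart from the other 5 oocyte libraries on the first principal component (21.5, which held 27.3% of the variance) and had the lowest mitochondrial share, 11.4%. Relative to all tested genes the list's median was 0.408, 0.247 without that library, and down to 0.144 with 1 further library left out. Nuclear-encoded respiratory chain genes did not pass (21 of 28 lower, median -0.17, adjusted p = 0.546), nor did antioxidant enzymes (7 of 8 lower, median -0.14, adjusted p = 0.241), though Gpx3 passed adjusted over the list alone (adjusted p = 0.00216). Heat shock chaperones had 6 of 8 members lower (median -0.15, adjusted p = 0.0910). Adjusted over the list alone, 2 of them passed, Dnaja1 and Hspe1 (-0.53, SE 0.12). Single members also passed adjusted over their list alone: the stress transcription factor Atf4 (-0.67, SE 0.12), the checkpoint kinase Chek1 (0.91, SE 0.21) and the mitophagy receptor Bnip3l (0.77, SE 0.16). Maternal effect genes (11 of 21 lower, median -0.02, adjusted p = 0.998) and the list of meiosis, cohesin and spindle checkpoint genes (10 of 17 higher, median 0.05, adjusted p = 0.546) did not pass.

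In cumulus cells, Socs3, a feedback inhibitor of cytokine signaling, was higher with PM2.5, at 4.47 ± 0.26 against 2.79 ± 0.15 (difference 1.69, SE 0.18). Gcsh, a subunit of the mitochondrial glycine cleavage system, was also higher, at 6.91 ± 0.03 against 5.83 ± 0.05 (1.08, SE 0.11). Plaa, a ubiquitin-binding protein, fell from 4.94 ± 0.20 to 2.91 ± 0.18, a difference of -2.03 (SE 0.16). The processed copies Tpm3-rs7 (2.65, SE 0.15) and Rps3a2 (0.95, SE 0.12), which RefSeq lists as pseudogenes, also rose. Limma gave adjusted p of 0.0135 for Socs3, 0.0133 for Gcsh, 0.00312 for Plaa, 0.000313 for Tpm3-rs7 and 0.0300 for Rps3a2. Plaa lies on chromosome 4 from 94565139 to 94603247, Socs3 on chromosome 11 from 117966079 to 117970336 and Tpm3-rs7 on chromosome 14 from 113314601 to 113316720 (mm10). Values of Tpm3-rs7 and Rps3a2 are uncertain, since reads can be shared with Tpm3 and Rps3a1. Tpm3 itself differed by -0.53 (SE 0.12, limma adjusted p = 0.176). The stromal and oviduct list means and S100a9 separated the same libraries, so differences of single genes here may also reflect other cells.

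In all, 8 of 4780 genes passed the threshold in cumulus cells, 7 higher and 1 lower. Of these, 5 were pseudogenes, 3 of them predicted genes, and the other 3 (Socs3, Gcsh and Plaa) code for proteins. At an unadjusted p under 0.05 there were 1114 genes, against 239 by chance, and 1257 genes (26.3%, against 10% by chance) had groups that did not overlap. The next 5 in each direction did not pass. Their differences were 0.96 for the secreted chaperone Clu, 1.21 for Tnni3, 1.31 for Enc1, 0.82 for Mlf1 and 1.09 for the respiratory chain subunit Ndufa4. In the other direction they were -0.82 for the epidermal growth factor-like ligand Ereg, -1.05 for the cholesterol exporter Abca1, -0.81 for the collagen cross-linking enzyme Lox, -0.82 for Rnf125 and -1.17 for Rtp4, with limma adjusted p from 0.0568 to 0.176. The number of genes changed by PM2.5 in cumulus cells rested on single libraries and on the model: it was 559 without PM2.5 replicate 1, which lay between the groups on the first principal component, 14 without filtered-air replicate 1, and 2236 with library quality weights. With the hemoglobin covariate, chosen after seeing the data, 4 genes passed.

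Of 28 lists tested in cumulus cells, 6 passed with the preset correlation and none with an estimated one. Nuclear-encoded genes of oxidative phosphorylation rose: 73 of 74 were higher, with a median difference of 0.48 (camera adjusted p = 6.3e-11; adjusted p = 0.758 with an estimated correlation). Relative to all tested genes the median was 0.396, and 0.218 after each library's trend with transcript length was removed. Examples are Ndufa4 (1.09, SE 0.18), Ndufc2 (0.63, SE 0.13), Atp5j (0.57, SE 0.14) and Ndufs8 (0.57, SE 0.14), and Ndufa4 alone passed adjusted over the list alone. Cytosolic ribosomal protein genes rose, with 70 of 79 higher and a median of 0.33 (adjusted p = 9.3e-05; adjusted p = 0.772 with an estimated correlation), led by Rpl36 (0.48, SE 0.16), Rps26 (0.55, SE 0.20), Rpl28 (0.48, SE 0.18) and Rpl32 (0.46, SE 0.17). Proteasome subunits rose by less, with 27 of 31 higher and a median of 0.19 (adjusted p = 0.0331; adjusted p = 0.758 with an estimated correlation), led by Psmb2 (0.64, SE 0.17), Psmb6 (0.44, SE 0.14), Psma2 (0.41, SE 0.13) and Psmc3 (0.46, SE 0.15). These rises came in the same exposed libraries in which the stromal and oviduct markers given above were higher and S100a9 lower. The median difference over all tested cumulus genes was 0.0865, which the ribosomal and proteasome medians include. No length-corrected values are given for the ribosomal and proteasome lists, so length bias was not examined for them.

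Immediate early genes, the first transcripts induced by growth factor and stress signals, rose in exposed cumulus cells, with 13 of 14 higher and a median of 0.63 (camera adjusted p = 0.000358; adjusted p = 0.758 with an estimated correlation). Adjusted over the list alone 9 passed, all higher, and over all genes none; the smallest p values were those of the mRNA-destabilizing Zfp36 (0.92, SE 0.16), Ier2 (0.94, SE 0.16), Junb (0.64, SE 0.13) and Btg2 (0.61, SE 0.14). Fos differed more within the exposed group, at 7.62, 6.99 and 0.58, than between groups. Genes of cumulus expansion, by which cumulus cells lay down a hyaluronan matrix before ovulation, fell: 9 of 11 were lower, with a median of -0.41 (adjusted p = 0.00458; adjusted p = 0.758 with an estimated correlation). Adjusted over the list alone 4 passed: Ereg (-0.82, SE 0.14), the related ligand Btc (3.97 ± 0.41 against 4.96 ± 0.15 in controls), the estrogen sulfotransferase Sult1e1 (-1.61, SE 0.39) and the prostaglandin synthase Ptgs2 (-0.75, SE 0.19). Antioxidant enzymes rose, with 13 of 15 higher and a median of 0.32 (adjusted p = 0.0331; adjusted p = 0.758 with an estimated correlation), and 3 passed adjusted over the list alone: Gpx1 (0.56, SE 0.15), Prdx4 (0.52, SE 0.14) and Txn1 (0.56, SE 0.16). The antioxidant call was lost without PM2.5 replicate 1 (adjusted p = 0.0857) and without filtered-air replicate 2 (adjusted p = 0.0730). The proteasome call was lost without PM2.5 replicate 2 (adjusted p = 0.126) and without filtered-air replicate 2 (adjusted p = 0.0684). The stromal and oviduct list means and S100a9 separate the same libraries, so these changes too may reflect other cells.

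**Figure D2:**
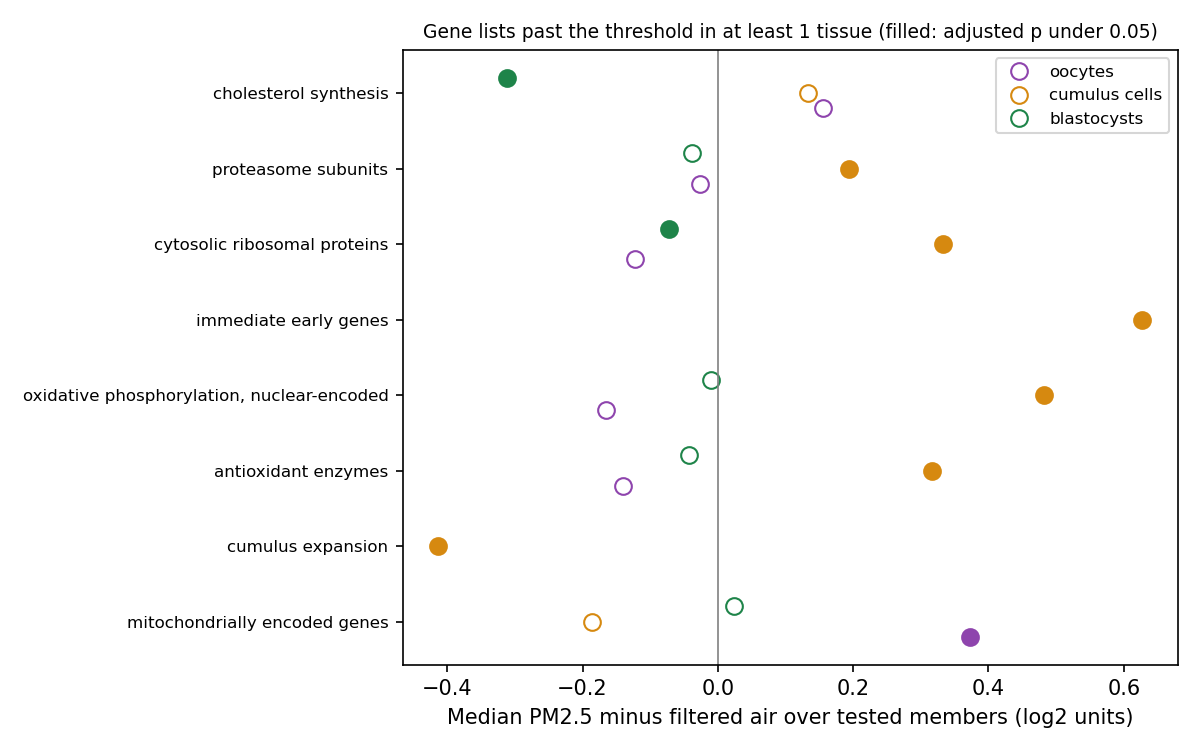
Each point is the median difference, PM2.5 minus filtered air in log2 units, over the tested members of a gene list, purple for oocytes, orange for cumulus cells and green for blastocysts, filled where camera with its preset correlation passed. Among the lists shown, which passed in at least 1 tissue, immediate early genes have the highest median in cumulus cells (0.63). Cholesterol synthesis is filled in blastocysts (-0.31).

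In blastocysts no gene passed the threshold among 4834 tested with limma, and 191 had an unadjusted p under 0.05, against 241.7 by chance. The groups did not overlap in 412 genes (8.52%, against 10% by chance). The genes with the smallest p were higher in exposed blastocysts for Srp72, a subunit of the signal recognition particle (1.63, SE 0.33), the Golgi GTPase Rab6a (1.35, SE 0.29), the epiblast co-receptor Tdgf1 (1.08, SE 0.26), Sdcbp2 (0.92, SE 0.23) and the alcohol dehydrogenase Adh1 (0.85, SE 0.22). They were lower for Crcp (-1.65, SE 0.32), Rnf19b (-1.49, SE 0.30), Scand1 (-1.11, SE 0.25), Slc35e4 (2.71 ± 0.17 against 3.71 ± 0.29 in controls) and the RNA-binding protein gene Ybx1 (-0.73, SE 0.17), with limma adjusted p from 0.726 to 0.998. Tdgf1 passed adjusted over the list of pluripotency markers alone (adjusted p = 0.0134), while that list did not pass (4 of 6 higher, median 0.25, adjusted p = 0.322). Leaving out 1 library gave 4 genes without PM2.5 replicate 2, 2 without PM2.5 replicate 3, 2 without filtered-air replicate 1 and 1 without filtered-air replicate 2.

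Of 26 lists tested in blastocysts, genes of cholesterol synthesis fell, with 14 of 17 lower and a median of -0.31 (camera adjusted p = 0.000169; adjusted p = 0.886 with an estimated correlation). Examples are the sterol demethylase Cyp51 (-0.53, SE 0.16), Nsdhl (-0.65, SE 0.21), Msmo1 (-0.52, SE 0.18) and Ebp (-0.40, SE 0.15), none of which passed adjusted over the list alone. Cytosolic ribosomal protein genes were lower in 62 of 79 cases, with a median of -0.07 (adjusted p = 0.0473; adjusted p = 0.886 with an estimated correlation), a call lost without PM2.5 replicate 2, without filtered-air replicate 1 (adjusted p = 0.913) or without filtered-air replicate 2 (adjusted p = 0.153). Trophectoderm markers did not pass (6 of 10 higher, median 0.01, camera adjusted p = 0.916). Of the 10 splits of the 6 blastocyst libraries, the real one included, 7 gave at least 2 lists past the threshold. The pair of libraries numbered 1 stood together on the first principal component, at -15.5 for PM2.5 and -15.8 for filtered air, with mitochondrial shares of 16.1% and 14.7% against 21.1% to 23.3% in the others.

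Whether the exposure difference itself differed between tissues was tested gene by gene. Between oocytes and cumulus cells 8 of 2027 genes passed, 2 with a higher and 6 with a lower difference in oocytes, and 309 had an unadjusted p under 0.05, against 101.4 by chance. Plaa differed by 2.13 (SE 0.31, limma adjusted p = 0.00571), Mrpl9 by 1.09 (SE 0.20), Ndufa4 by -1.14 (SE 0.22) and the mitochondrial chaperonin Hspe1 by -0.96 (SE 0.18), the last 3 with a limma adjusted p of 0.0277. Pfdn5 (-1.03) and Gpx3 (-1.37) did not pass (limma adjusted p = 0.0737). After median centring of each library 3 genes passed, 2 higher and 1 lower. With 1 library left out the count went from 1 (without oocyte PM2.5 replicate 2 or cumulus PM2.5 replicate 2) to 63 (without cumulus PM2.5 replicate 1). Between cumulus cells and blastocysts 9 of 3479 genes passed, 5 higher and 4 lower in cumulus cells. Tpm3-rs7 differed by 2.44 (SE 0.24), Plaa by -2.26 (SE 0.30), Gcsh by 1.37 (SE 0.20), Srp72 by -2.10 (SE 0.36), Rab6a by -2.14 (SE 0.39) and Rps3a2 by 0.92 (SE 0.18), with limma adjusted p from 3.7e-05 to 0.0266. Median centring gave 4 higher and 5 lower. Without cumulus PM2.5 replicate 1 there were 93, and without blastocyst PM2.5 replicate 1 there were 15.

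Between oocytes and blastocysts no gene of 2054 passed in limma, with 136 at an unadjusted p under 0.05 against 102.7 by chance. The smallest adjusted p values were those of Timm10 (1.69, SE 0.30) and Mrpl9 (1.02, SE 0.20), both 0.0700. Srp72 (-1.67), Dnaja1 (-1.10), Rab6a (-1.64) and Skp1a (-0.67) followed. No gene was past the threshold in more than 1 tissue. Of the 2027 genes tested in both oocytes and cumulus cells, 3 passed in oocytes and 2 in cumulus cells, and blastocysts had 0. With so few, the lack of overlap says nothing about whether responses are shared. Tpm3-rs7, past the threshold in cumulus cells, also differed by 1.91 in oocytes (3.57 ± 0.19 against 1.66 ± 0.32), where its mean was too low for it to be tested. Across genes, which are not independent replicates, the differences of oocytes and cumulus cells correlated at r = 0.085, those of oocytes and blastocysts at 0.010 and those of cumulus cells and blastocysts at -0.058. With 1 library left out these ranged from 0.014 to 0.176, from -0.024 to 0.037 and from -0.192 to 0.095, so the last 2 took both signs. Among genes with a mean log2 value of at least 5 the correlation of PM2.5 effects across genes, oocytes and cumulus cells, was 0.254. As lists, oxidative phosphorylation genes differed in exposure response between oocytes and cumulus cells (camera adjusted p = 1.1e-06; adjusted p = 0.349 with an estimated correlation) and between cumulus cells and blastocysts (adjusted p = 4.1e-06; adjusted p = 0.686 with an estimated correlation). Between oocytes and cumulus cells the other lists past the threshold were, with the adjusted p at the estimated correlation in brackets, cytosolic ribosomal proteins at 0.000288 (0.478), mitochondrially encoded genes at 0.000443 (0.478), antioxidant enzymes at 0.00750 (0.155), proliferation at 0.0126 (0.243) and proteasome subunits at 0.0299 (0.478). Of these, only mitochondrially encoded genes had the higher difference in oocytes. Between cumulus cells and blastocysts they were cytosolic ribosomal proteins at 5.9e-05 (0.744), cholesterol synthesis at 0.0292 (0.598), proteasome subunits at 0.0336 (0.598), antioxidant enzymes at 0.0378 (0.598) and mitochondrially encoded genes at 0.0378 (0.744). Here only mitochondrially encoded genes had the lower difference in cumulus cells. Between oocytes and blastocysts mitochondrially encoded genes passed alone, at 0.0397 (0.925).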

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

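The tests of pseudogenes and the splits within a single tissue were chosen after the result was seen, and the relabelings across 2 tissues were planned. The genes named below for a difference between tissues are those in which a test of the difference itself passed. The 8 genes whose response differed between oocytes and cumulus cells included Plaa (2.13), which fell in cumulus cells, at -2.03, and differed by 0.10 in oocytes. They also included Mrpl9 (1.09), which rose in oocytes, and Ndufa4 (-1.14) and Hspe1 (-0.96), whose differences were 1.09 and 0.43 in cumulus cells and -0.06 and -0.53 in oocytes. Of 100 relabelings within the 2 tissues, the real one included, 1 gave as many genes, and the highest other gave 4. This share was not adjusted for the other pairs of tissues, and the libraries may not be separate animals, so chance is not excluded. The count still rests on single libraries: it was 1 without oocyte PM2.5 replicate 2 or without cumulus PM2.5 replicate 2.

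The 9 genes whose response differed between cumulus cells and blastocysts included Tpm3-rs7 (2.44), Plaa (-2.26), Gcsh (1.37), Srp72 (-2.10), Rab6a (-2.14), Rps3a2 (0.92), Ndufa4 (1.16) and Rnf125 (-1.24). Of 100 relabelings 5 gave as many genes, so chance is not excluded. The highest other gave 165, many times the real count, for a reason that was not tested. The highest other splits within cumulus cells or within blastocysts gave 4 and 2 genes. Between oocytes and blastocysts the real count was 0 and the highest other 8. All 100 relabelings must reach a count of 0, so this says nothing about chance.

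Of the 17 genes past the threshold in oocytes and cumulus cells, 6 were pseudogenes (35.3%, against 6.11% of tested genes, exact one-sided hypergeometric test, p = 0.000349). The test takes genes as independent, while Gm12245 and Gm4322 had similar means in cumulus cells (6.71 and 6.64 exposed, 2.25 and 2.34 control). The excess lay in cumulus cells, with 5 pseudogenes of 8 genes, against 1 of 9 in oocytes. This excess is what reads shared with near-identical copies could produce, and it does not show which copy changed. A strain difference between the exposed and control mice is a further candidate explanation, though the labels give C57BL/6 for all 18 libraries. It would be expected to show in blastocysts too, but not at full size if the fathers did not share it. Only 4 of the 6 were tested there, since Gm12245 and Gm4322 stood at 0.37 and 0.41. Over these 4 the median, signed by the direction of the call, was 0.00752, and 0 of the 4 were at least 0.5 times as large. Tpm3-rs7 stood at 6.44 in control blastocysts against 2.58 in control cumulus cells, a level at which other reads could hide a difference. It differed by 1.91 in oocytes, in the same direction as in cumulus cells. Tpm3 moved the other way, by -0.69 in oocytes, where it was too low to be tested, and by -0.53 in cumulus cells. Gm15542 differed by -0.95 in oocytes, 0.04 in cumulus cells and 0.02 in blastocysts. That goes against a strain difference if the tissues came from the same mice, which the sources used here do not say. Rps3a2 was higher by 0.95 in cumulus cells and by 0.44 in oocytes, the same direction in both, and differed by 0.03 in blastocysts. Rps3a1 differed by -0.12 in cumulus cells, -0.35 in oocytes and -0.04 in blastocysts. Opposite signs of Tpm3 and Rps3a1 and their copies are what shared reads could also produce, which was not tested. For the 6 as a set, with Gm12245 and Gm4322 unmeasured outside cumulus cells, a strain difference cannot be told apart from an exposure effect for these genes; the requirement on how many must be measured was added after the value was seen. An exposure effect on the pseudogenes or their parents stays open and untested.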

How the results depend on the processing

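The looser filter, protein-coding genes alone, the hemoglobin covariate, leaving out both blastocyst libraries numbered 1, and every setting of the correlations were chosen after seeing the data. Reversal was checked for genes named in a tissue (past the threshold or smallest unadjusted p) or for a pair of tissues. None reversed under any setting. Groups of those named in a tissue did not overlap, so leaving out 1 library could not reverse them. Predicted genes and genes named only as members of a list or marker list were not checked. The correlation of oocytes with blastocysts and that of cumulus cells with blastocysts took both signs. Where no cause is given below, the cause was not tested. The planned count tests (edgeR and DESeq2 on whole reads) were not run, because whole reads could not be recovered. Of the named genes past the threshold, Eps8 passed in 16 of 16 settings, Pacsin2 in 12 of 16, Mrpl9 and Neil3 each in 10 of 17, Gna14 in 8 of 17 and Dnaja1 in 8 of 16 in oocytes. In cumulus cells Tpm3-rs7 passed in 16 of 16, Plaa in 16 of 17, Socs3 in 12 of 17, Gcsh in 12 of 18 and Rps3a2 in 8 of 17.

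The 9 genes changed by PM2.5 in oocytes became 5 without a filter, 4 at a mean log2 of at least 5, where fewer genes were tested, 20 with library quality weights, 27 with all 18 libraries in 1 fit and 17 at a mean log2 of at least 1. Leaving out 1 library gave 2 to 11, with 3 without filtered-air replicate 1 and 2 without filtered-air replicate 3. The 8 genes changed by PM2.5 in cumulus cells became 5 without a filter, 4 at a mean log2 of at least 5, 2236 with quality weights (1315 higher, 921 lower), 103 with all 18 libraries, 3 among protein-coding genes and 4 with the hemoglobin covariate. Leaving out 1 library gave 6 to 559, with 559 without PM2.5 replicate 1 and 14 without filtered-air replicate 1. The count of 0 genes changed by PM2.5 in blastocysts became 1 without a filter, 2 with all 18 libraries, 2 at a mean log2 of at least 1 and 4 without both libraries numbered 1, and 0 to 4 with 1 library left out.

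Of the gene lists past the threshold in oocytes, in cumulus cells and in blastocysts (1, 6 and 2), 0 passed in each tissue with an estimated correlation and 0 with fry. Leaving out 1 library gave 1 to 2, 5 to 8 and 1 to 3. The 8 genes whose PM2.5 effect differs between oocytes and cumulus cells became 2 at a mean log2 of at least 5 in both, 3 after median centring, 336 with quality weights and 4 with only the 12 libraries, and 1 to 63 with 1 library left out. Without oocyte PM2.5 replicates 1, 2 and 3 there were 5, 1 and 4, without oocyte filtered-air replicates 1 and 3 there were 14 and 4, without cumulus PM2.5 replicates 1, 2 and 3 there were 63, 1 and 3, and without cumulus filtered-air replicates 1, 2 and 3 there were 29, 2 and 2. The count of 0 genes whose PM2.5 effect differs between oocytes and blastocysts became 2 at a mean log2 of at least 5, 3 after median centring and 11 with quality weights, and 0 to 7 with 1 library left out, the 7 without blastocyst PM2.5 replicate 1. The 9 genes whose PM2.5 effect differs between cumulus cells and blastocysts became 5 at a mean log2 of at least 5, 721 with quality weights and 4 with only the 12 libraries, and 6 to 93 with 1 library left out, with 93 without cumulus PM2.5 replicate 1 and 15 without blastocyst PM2.5 replicate 1.

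The correlation of PM2.5 effects across genes, oocytes and cumulus cells, was 0.254 at a mean log2 of at least 5 and 0.0144 to 0.176 with 1 library left out. The correlation of PM2.5 effects across genes, oocytes and blastocysts, was -0.0219 and -0.0241 to 0.0368. The correlation of PM2.5 effects across genes, cumulus cells and blastocysts, was -0.179 and -0.192 to 0.0948. Median centring cannot change a correlation and says nothing about its stability.

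The replicate numbers were not taken to pair the libraries, since in no tissue did all same-numbered libraries deviate together. The deviations of same-numbered libraries correlated at -0.09, -0.07 and -0.07 in oocytes, -0.21, -0.24 and -0.16 in cumulus cells and 0.18, 0.03 and -0.03 in blastocysts. The 2 blastocyst libraries numbered 1 did deviate together, and they stood together on the first principal component (-15.5 and -15.8). With the replicate block, genes changed by PM2.5 in oocytes numbered 3, genes changed by PM2.5 in cumulus cells 3 and genes changed by PM2.5 in blastocysts 0. Genes whose PM2.5 effect differs between oocytes and cumulus cells numbered 1 with the block, those between oocytes and blastocysts 0, and genes whose PM2.5 effect differs between cumulus cells and blastocysts 3. Of lists, 1, 7 and 2 passed with the block.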

Other observations

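Other groups of genes in cumulus cells held members that passed adjusted over their list alone, though not over all genes. Metallothioneins Mt1 (0.82, SE 0.21) and Mt2 (0.82, SE 0.21), which bind metals, were higher in exposed cumulus cells, while the zinc importer Slc39a10 differed by -0.45 (SE 0.15), and the metal response list did not pass (4 of 7 higher, camera adjusted p = 0.919). The chemokine Cxcl1 (1.28, SE 0.35) and the NF-kB inhibitor Nfkbia (0.66, SE 0.19) were 2 of 3 tested members of the inflammatory list, which was too short to test. Of granulosa markers, Inha (0.93, SE 0.16) and Hsd17b1 (0.54, SE 0.17) passed. Of p53 targets, Ccng1 (-0.75, SE 0.17) and Trp53inp1 (-0.88, SE 0.24) were lower and Btg2 (0.61, SE 0.14) was higher. Of the aryl hydrocarbon receptor targets, which respond to polycyclic hydrocarbons, only Tiparp (0.08, SE 0.13) and Cyp1b1 (0.03, SE 0.21) of 10 were expressed highly enough to test in cumulus cells. In each group of 3 libraries 28 to 55 genes that reached a log2 value of 4 had a gap of more than 3 between libraries of the same group; in filtered-air cumulus cells Gja1 stood at 6.69, 6.73 and 0.99.

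The counts of other splits of the genes, the test of oocyte RNA and both tests of mitochondrially encoded genes in this part were chosen after the result was seen; the tests of length and red blood cells were chosen after the higher respiratory chain genes and the hemoglobin levels had been seen, though before their own outcomes, and the splits of lists were planned. Splits of 6 libraries number 10, too few for a share under 0.05. In oocytes 1 of the 10 splits gave as many genes as the real 9, the real one included, and the highest other gave 3. In cumulus cells 1 of 10 gave as many as the real 8, and the highest other gave 4. In blastocysts all 10 gave at least the real 0, and the highest other gave 2. For lists, 9 of 10 splits of the oocyte libraries gave as many as the real 1, and the highest other gave 4. In cumulus cells 1 of 10 gave as many as the real 6, with a highest other of 5, and in blastocysts 7 of 10 gave as many as the real 2, with a highest other of 4.

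The higher nuclear-encoded respiratory chain genes in exposed cumulus cells had a median of 0.396 above that of all tested genes. Removing each library's trend with transcript length left 0.218 (0.158 to 0.256 with 1 library left out). The camera adjusted p was then 2.8e-07 with the preset correlation. Before the trend was removed the list did not pass with an estimated correlation (camera adjusted p = 0.758). Length bias may therefore account for at least part of the difference. The lengths were those of the longest annotated transcript of an earlier mouse build, so the trend may not have been removed in full. The remainder thus does not exclude length bias as the whole cause. With hemoglobin as a covariate the median was 0.424 (0.307 to 0.549 with 1 library left out), which argues against red blood cells. Oocyte RNA would lower these genes, since they stood at a median of -3.51 in control oocytes relative to control cumulus cells, with 94.6% lower. Other cells stay open and were not tested, and the hemoglobin covariate does not stand for leukocytes. The means of the stromal and oviduct lists, though not all members, were higher in each exposed cumulus library. Differences in cell state or RNA yield between libraries were not tested either, and a response of cumulus cells to PM2.5 stays open as a hypothesis.

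The higher mitochondrially encoded genes in exposed oocytes had a median of 0.408 above that of all tested genes. Without filtered-air replicate 3 it was 0.247, and 0.144 to 0.367 with any 1 further library left out, which argues against that library as the whole cause. Cumulus RNA left on that library's oocytes was tested with 50 abundant cumulus genes chosen in the other 5 oocyte libraries. Their median was 0.84 there against 0.92 in the highest other oocyte library, a difference of -0.0799, and 7.73 in cumulus libraries. Mitochondrially encoded genes were higher in cumulus than in oocyte libraries by a median of 0.211, with 6 lower. Filtered-air replicate 3 nevertheless correlated with cumulus PM2.5 replicate 1 at 0.555, against 0.536 to 0.544 for the other 5 oocyte libraries. These values do not decide whether cumulus RNA was left on the oocytes. An exposure effect on mitochondrial transcripts or on oocyte quality stays open as a hypothesis, and it may also be a difference in capture between libraries, which was not tested. At least 1 list passed in 9 of 10 splits of the oocyte libraries, so a list past the threshold is not particular to the exposure grouping.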
